A study of Rattus norvegicus with 6 samples.

How the data were processed

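RNA from 6 cultures of newborn Sprague-Dawley rat cells was measured on expression arrays, 3 of SKPs (skin-derived precursors, from back skin) and 3 of NSCPs (nerve-derived Schwann cell precursors, from sciatic nerve). The series' design text calls the 3 cultures of each kind independent isolates, so the replicates are separate cultures. Per the labels' protocols, SKPs grew as spheres at 50000 cells/ml with EGF at 20 ng/ml, FGF2 at 40 ng/ml and 2% B27, and NSCPs grew in medium with 25 ng/ml neuregulin-1β, 5 μM forskolin and 2% N2 on plates coated with 4 μg/ml laminin and 30 μg/ml poly-D-lysine. The growth text covers both cultures in a single run-on passage that is the same on every sample, and B27 was read as part of the SKP medium. Tissue of origin, medium and growth form therefore change together between the groups and cannot be separated in these arrays. Per the labels' protocols, cDNA was made from 400 ng of total RNA with a whole-transcript kit. Scan dates and array batches are not given in the sources used here.

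The deposited values are log2 expression values, 1 per probe set and array, made by the authors with the oligo package and RMA (background correction, quantile normalization and summary of probes into probe sets), per the submitters' processing notes, which state no versions. Quantile normalization gives the arrays nearly the same distribution of values, so a shift of all genes in 1 group would not be seen. The value table held 36685 probe sets. The platform's gene table paired 18511 of them with 1 gene symbol, 575 with several and left 17599 without a name here. By Entrez ID, 18394 of the 18511 symbols were matched to RefSeq (assembly GRCr8, used for names only) and 117 were not and kept the table's symbol. No coordinates are given, because the build behind the probe sets is not given in the sources used here.

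The deposited values were used without further normalization or filtering. For the 291 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was kept, leaving 18166 genes. NSCPs were compared with SKPs by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. A gene is called higher or lower below when it passed that threshold. Differences are NSCPs minus SKPs on the log2 scale with the standard error (SE) of the fit, and levels are means ± SD over 3 arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

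Before the data were examined, 33 gene lists with 722 distinct genes were fixed from textbook knowledge, covering the expected cell types, other cell types that skin or nerve could bring along, secreted ligands, receptors, positional genes, targets of the media's factors, and general cell states. Of these genes 86 have no probe set with a single symbol and were not analysed here. Lists with at least 3 measured members (31) were tested with limma's camera with a preset correlation between genes of 0.01, which asks whether a list moved relative to all other genes, with Benjamini-Hochberg adjustment over the 31 lists. The same test with an estimated correlation is given beside it, and limma's fry asked whether the genes of a list move on balance in 1 direction.

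Genes are named by a rule that was also fixed beforehand: the 12 with the largest difference in each direction among called genes whose groups did not overlap, leaving out provisional symbols; Pdgfa and Osm; up to 5 called members per list with the largest difference (12 for ligands, 8 for receptors and Hox genes), or where fewer than 3 members were called up to 3 with the highest mean; and genes whose probe sets disagree. Genes named outside this rule are said to be chosen after their values were seen.

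No detection calls were used. As an empirical background, the 95th percentile of the means of 227 olfactory and vomeronasal receptor genes was taken, which was 5.32 on the log2 scale. A group mean not above it is called within background, and a fold against such a mean rests on a background level. The number of arrays limits the precision. On simulated data 200 of 18166 genes were changed between 3 and 3 arrays. The fit recovered 10.4% of changes of 0.5 on the log2 scale, 66.4% of changes of 1, 95.6% of changes of 2 and 100% of changes of 4. False calls made up 4.31% of all calls. Far more genes, 7945, passed in the real arrays, which eases the adjusted threshold. The simulated shares therefore do not measure the recovery in the real comparison.

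Alternatives covered each array left out in turn, the replicate number as a block, renewed quantile normalization, median centring, filters on dim genes, the mean of all probe sets of a gene, adjustment over all probe sets, a trended and robust prior, array weights, an estimated correlation or ranks in camera, an adjusted p under 0.01, and limma's treat. A ligand list without genes that leukocytes also express was added after seeing the data.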

Results

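Expression was measured in cultured SKPs from the back skin and NSCPs from the sciatic nerve of newborn rats, with 3 independent isolates of each and 1 array per isolate. SKPs are sphere-forming precursors of the dermis, and NSCPs are cultured precursors of Schwann cells, the glia of peripheral nerves. The series title places the data in work on paracrine factors of nerve-derived Schwann cell precursors in digit tip regeneration, so secreted ligands and their receptors are described beside the identity of the cells. From 67.3% to 69.1% of the genes on each array lay above the background level of 5.32. Pearson correlations across genes were 0.984 to 0.993 between arrays of the same kind and 0.872 to 0.888 between SKP and NSCP arrays, and the first principal component, which separated the groups, held 88.7% of the variance.

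Of 18166 genes, 7945 differed between the cell types, 4569 higher and 3376 lower in NSCPs. Peripheral myelin protein gene Pmp2, which encodes a fatty acid binding protein of myelin, was among the genes with the largest excess in NSCPs, and the matrix proteoglycan genes Lum and Dcn and the lysozyme gene Lyz2 were among those with the largest deficit. These genes are not ranked, because the lower group's mean lay within background. At least 2-fold differences were found for 3167 genes, 1354 higher and 1813 lower in NSCPs, and differences of at least 16-fold for 64 higher and 217 lower. In 56.6% of genes the 3 arrays of each group did not overlap, against 10% by chance. Among the genes at least 2-fold lower in NSCPs, 570 had an NSCP mean within background, and among those at least 2-fold higher 161 had an SKP mean within background. Of the 7945 called genes 769 were within background in both groups. With limma's treat, which tests against a 2-fold change itself, 1758 genes passed.

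Pmp2 stood at 12.76 ± 0.18 (SD, n = 3) in NSCPs and 5.13 ± 0.18 (SD, n = 3) in SKPs, a difference of 7.64 (SE 0.15, adjusted p = 2.15e-08). Gjc3, which encodes a connexin of myelinating glia, was 38.5-fold higher. The other genes with the largest excess in NSCPs were Clca4l (7.08 on the log2 scale), Sostdc1, which encodes a secreted antagonist of BMP and Wnt signals (5.56), Palmd (5.49), the tubulin gene Tubb2b (5.46), Slc35f1 (5.39), the amino acid transporter gene Slc38a1 (5.31), Plekhb1 (5.30), the protease gene Tmprss5 (5.20), the ATP-gated channel gene P2rx7 (5.18) and the microRNA gene Mir19b2 (5.10). Of these 12, Pmp2, Clca4l, Palmd, Slc38a1, Gjc3 and Mir19b2 had SKP means within background. Clca4l, Tubb2b and Mir19b2 have close relatives whose transcripts their probes may share, so their identity is uncertain.

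In the opposite direction, the matrix genes Lum, Dcn and Mgp were lower in NSCPs by differences of -8.91, -8.49 and -7.62. Lum stood at 12.14 ± 0.09 (SD, n = 3) in SKPs and 3.23 ± 0.62 (SD, n = 3) in NSCPs. Lyz2, which encodes lysozyme, differed by -8.80 (SE 0.17). Further genes of leukocytes were among the same 12: the pattern receptor gene Clec7a (-7.57), Arhgdib (-7.50), the NADPH oxidase gene Cybb (-7.29) and Lilrb4 (-7.24). The collagenase gene Mmp13 (-7.41), the proenkephalin gene Penk (-7.11), the semaphorin gene Sema3d (-7.06) and Serpinf1 (-6.96) completed them. NSCP means were within background for all 12 except Penk and Serpinf1, so the other differences rest on a background level and give no order.

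To check the nerve label, markers of the Schwann cell lineage were examined. Of 18 measured members 14 were higher and 2 lower in NSCPs, also when adjusted over the list alone. The adhesion genes L1cam and Cadm4 were 30.3-fold and 29.3-fold higher, and Erbb3, which encodes a neuregulin receptor, was 27.5-fold higher (11.35 ± 0.09 against 6.57 ± 0.21, SD, n = 3 each). Cdh19 was 23.1-fold and Mal 23.1-fold higher. The 2 lower members, named after their values were seen, were Gfra3 (-2.20) and Gap43 (-0.69). The list median was 2.87 and camera's adjusted p was 9.59e-06, but the adjusted p was 0.130 with an estimated correlation.

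Genes of myelin and its regulators had 13 members higher and 4 lower among 18, also when adjusted over the list alone. Mbp, which encodes myelin basic protein, was 32.1-fold higher (SE 0.16 on the log2 scale), the tight junction gene Cldn19 27.7-fold, Pou3f1, which encodes a transcription factor of promyelinating Schwann cells, 20.6-fold with its SKP mean within background, and the glycolipid synthesis gene Ugt8 14.1-fold. Lower members, named after their values were seen, were Nfatc4 (-2.32), Tspan2 (-2.26), Egr2 (-1.91), which encodes a central transcription factor of myelination, and Drp2 (-1.57). By camera the list had an adjusted p of 0.00251, and the adjusted p was 0.234 with an estimated correlation.

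Repair Schwann cell genes, which respond to nerve injury, had 11 members higher and 4 lower among 17, also when adjusted over the list alone, and the list was not called (adjusted p = 0.0913 by camera). Shh was 12.3-fold higher, the adhesion gene Mcam 10.7-fold, Sox2 7.98-fold and Btc, which encodes an EGF receptor ligand, 4.89-fold, while Runx2 was lower (-2.75). Neural crest genes had 9 higher and 4 lower among 18, also when adjusted over the list alone, and were not called (adjusted p = 0.119). Sox10, which encodes a transcription factor of neural crest and glia, was 8.56-fold higher at 10.52 ± 0.21 (SD, n = 3), and its SKP mean of 7.42 ± 0.22 (SD, n = 3) lay above background. Id3 and Sox5 were higher by 2.95 and 2.40, and Zic1 (-3.97, NSCP mean within background) and Snai1 (-2.30) were lower.

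To check the skin label, genes of dermal fibroblasts and mesenchyme were examined. Among 22 members 19 were lower and 0 higher in NSCPs, also when adjusted over the list alone; limma at an unadjusted p under 0.05 gave 0 higher as well. Beside Lum and Dcn, the lower members included Pdgfra, the gene of PDGF receptor alpha, at 118-fold lower (5.44 ± 0.02 in NSCPs against 12.33 ± 0.01 in SKPs, SD, n = 3 each), the mesenchymal transcription factor gene Prrx1 (-6.43) and the fibroblast activation gene Fap (-6.13). In NSCPs the means of Lum, Dcn, Prrx1 and Fap were within background, so these members have no order. Camera's adjusted p was 3.19e-13, and the adjusted p was 0.130 with an estimated correlation. Dermal papilla genes, of the mesenchyme that instructs hair follicles, had 11 lower and 4 higher among 18 (11 and 5 when adjusted over the list alone). The proteoglycan gene Vcan was 93.9-fold lower, and Rspo3 (-5.73), Crabp1 (-4.46), Alx4 (-3.91) and Trps1 (-3.43) were lower too, Rspo3 with an NSCP mean within background. That list had an adjusted p of 2.87e-04 by camera, and an adjusted p of 0.234 with an estimated correlation.

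SKP markers went both ways, with 7 of 14 lower and 4 higher in NSCPs, also when adjusted over the list alone. Pdgfra, Vcan, the fibronectin gene Fn1 (37.5-fold) and Wnt5a (11.5-fold) were lower. Sox2 was higher in NSCPs, at 10.65 ± 0.05 against 7.65 ± 0.95 (SD, n = 3 each), and so were Nes (2.23), Cd9 (1.04) and Ncam1 (0.88), named after their values were seen. The list was called lower at an adjusted p of 0.0363, with an adjusted p of 0.388 with an estimated correlation and of 0.0528 without SKP replicate 1. It also missed the threshold on ranks (0.312), with the filters on dim genes (0.0868 and 0.0980) and with the trended prior (0.0513).

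Positional genes of limb and body wall had 11 members lower and 3 higher among 18 (11 and 4 when adjusted over the list alone). Tbx15, which encodes a T-box factor of dorsal dermis and limb, was lower in NSCPs by a difference of -6.11, and Zic1, Alx4, Shox2 (-3.08) and Tbx18 (-2.96) were lower. The NSCP means of Tbx15, Zic1, Shox2 and Tbx18 were within background. Camera gave an adjusted p of 2.76e-04, against an adjusted p of 0.234 with an estimated correlation. Hox genes, which mark position along the body axis, had 7 higher and 10 lower among 31, also when adjusted over the list alone, with Hoxa6 (-4.25), Hoxc8 (-2.82), Hoxa5 (-2.75) and Hoxa9 (-2.08) lower, Hoxa6 and Hoxa5 with NSCP means within background. Hoxc8 remained at 8.41 ± 0.18 (SD, n = 3) in NSCPs. As a list the Hox genes were not called (adjusted p = 0.0977; 0.0359 among genes above the median of all probes), and their median of 0.07 and mean of -0.48 differed in sign.

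**Figure D1:**
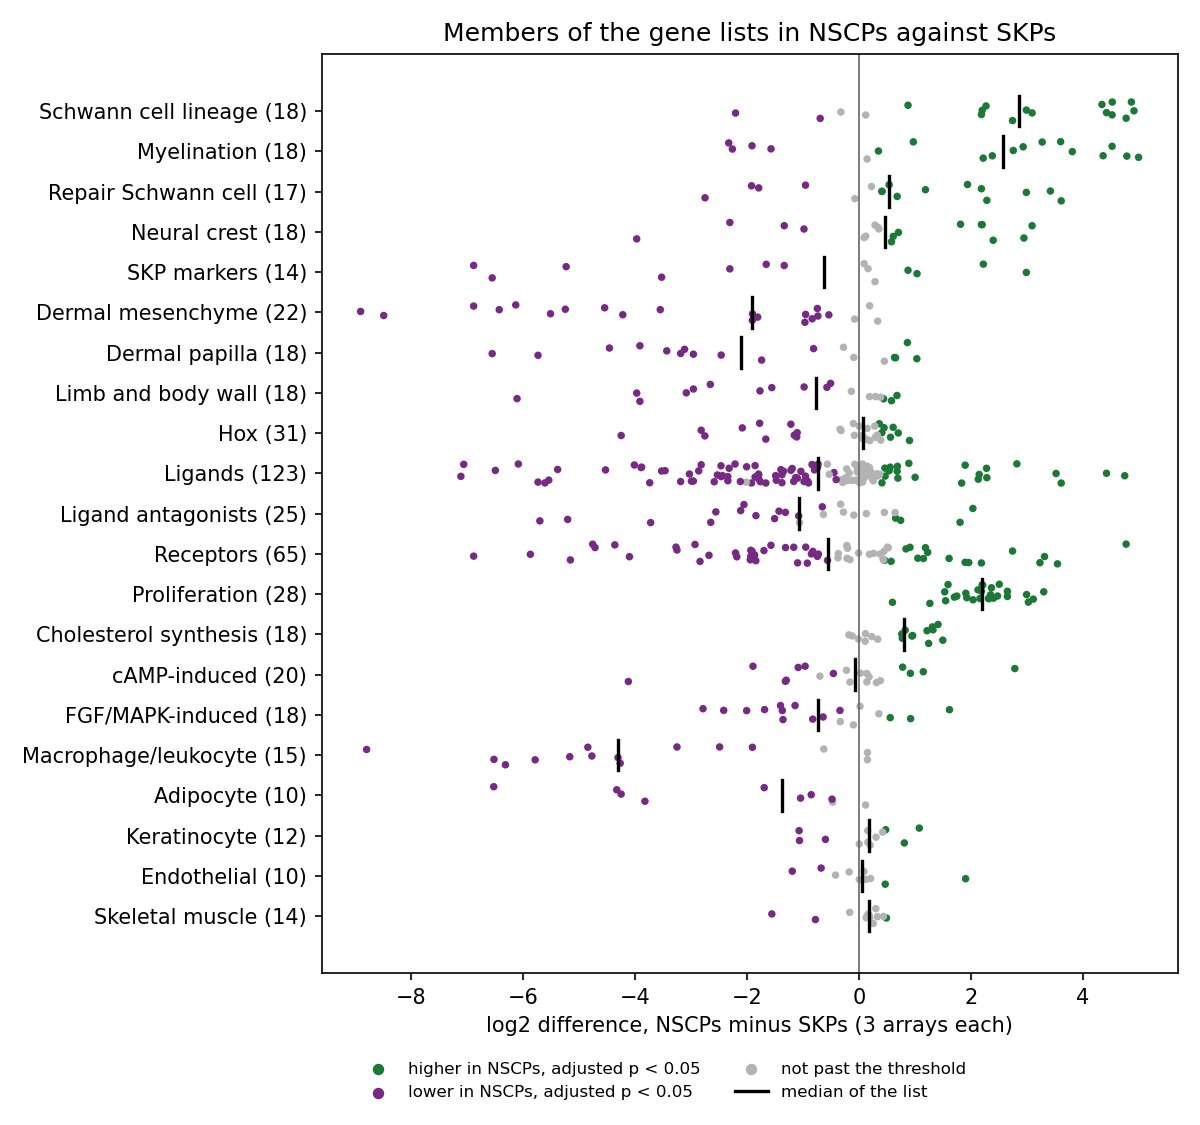
Each point is a gene, placed by its log2 difference (NSCPs minus SKPs, 3 arrays each), for 21 of the fixed gene lists with the number of measured members in brackets; colour marks direction among called genes, and the black bar is the list's median. The 28 proliferation genes all lie to the right of 0 (median 2.21), and the macrophage list has its median at -4.30.

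Secreted ligands were the genes closest to the question in the series title. Of 123 measured ligand genes 85 differed, 21 higher and 64 lower in NSCPs (21 and 66 when adjusted over the list alone). Hbegf, which encodes an EGF receptor ligand, was higher in NSCPs by 4.75, at 11.09 ± 0.14 against 6.33 ± 0.15 (SD, n = 3 each). Dhh, the hedgehog ligand gene of Schwann cells, was 21.5-fold higher at 10.04 ± 0.38 against 5.61 ± 0.25 (SD, n = 3 each). Pdgfa, which encodes a ligand of PDGF receptor alpha, was 4.45-fold higher in NSCPs at 9.79 ± 0.11 against 7.63 ± 0.10 (SD, n = 3 each; SE 0.12, adjusted p = 2.25e-06).

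Osm, which encodes the cytokine oncostatin M, was at 6.91 ± 0.11 in NSCPs and 7.23 ± 0.26 in SKPs (SD, n = 3 each), above background in both. Its difference of -0.32 did not pass (adjusted p = 0.125), with a 95% interval from -0.68 to 0.03. Among the ligand genes with the largest measured deficit in NSCPs were Penk, Sema3d, the osteopontin gene Spp1 (-6.50), the insulin-like growth factor gene Igf1 (-6.09), the Wnt amplifier gene Rspo3, the activin gene Inhba (-5.61), Angpt1 (-5.54), the cytokine gene Il18 (-5.38), the chemokine gene Cxcl16 (-4.53) and Pdgfd (-4.01). The NSCP means of Sema3d, Igf1, Rspo3, Angpt1, Il18, Cxcl16 and Pdgfd were within background, so their differences rest on a background level and give no order. Of the 15 measured macrophage and leukocyte markers 12 were lower in NSCPs as well. After removal of 27 ligands that leukocytes also express, an alternative chosen after seeing the data, 63 of 96 differed, 19 higher and 44 lower, and the list's median moved from -0.74 to -0.24. The ligand list had an adjusted p of 1.87e-07 by camera, and the adjusted p was 0.130 with an estimated correlation.

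Receptor genes had 17 members higher and 33 lower in NSCPs among 65 (18 and 33 when adjusted over the list alone). Some receptors for ligands named above were among those with the largest differences: Pdgfra was 118-fold lower in NSCPs, Osmr, which encodes the oncostatin M receptor, differed by -4.76 (6.68 ± 0.30 against 11.43 ± 0.16, SD, n = 3 each), and Egfr 17.1-fold lower (5.40 ± 0.30 against 9.50 ± 0.45, SD, n = 3 each). The collagen receptor gene Ddr2 (-5.87), Il1r1 (-5.15), Epha7 (-4.71) and Epha3 (-4.36) were also lower, with NSCP means within background for Ddr2, Epha7 and Epha3, and Erbb3 was higher in NSCPs. Receptors of other named ligands differed less or in the other direction, with Pdgfrb, for Pdgfd, at -1.31 and Tek, for Angpt1, higher in NSCPs by 1.91 with its SKP mean within background. For receptors camera gave an adjusted p of 3.28e-04, and the adjusted p was 0.130 with an estimated correlation. Secreted antagonists and binding proteins had 13 lower and 4 higher among 25 (13 and 5 when adjusted over the list alone). Lower members were the Wnt antagonist genes Frzb (-5.70) and Sfrp2 (-3.72), the IGF binding protein genes Igfbp4 (-5.20) and Igfbp5 (-2.55), and Ltbp2 (-2.65). The NSCP mean of Ltbp2 was within background. The antagonist gene Sostdc1, higher in NSCPs by 5.56, was not a member of this list, whose largest difference upward was 2.04. This list had an adjusted p of 3.56e-04 by camera and an adjusted p of 0.130 with an estimated correlation.

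**Figure D2:**
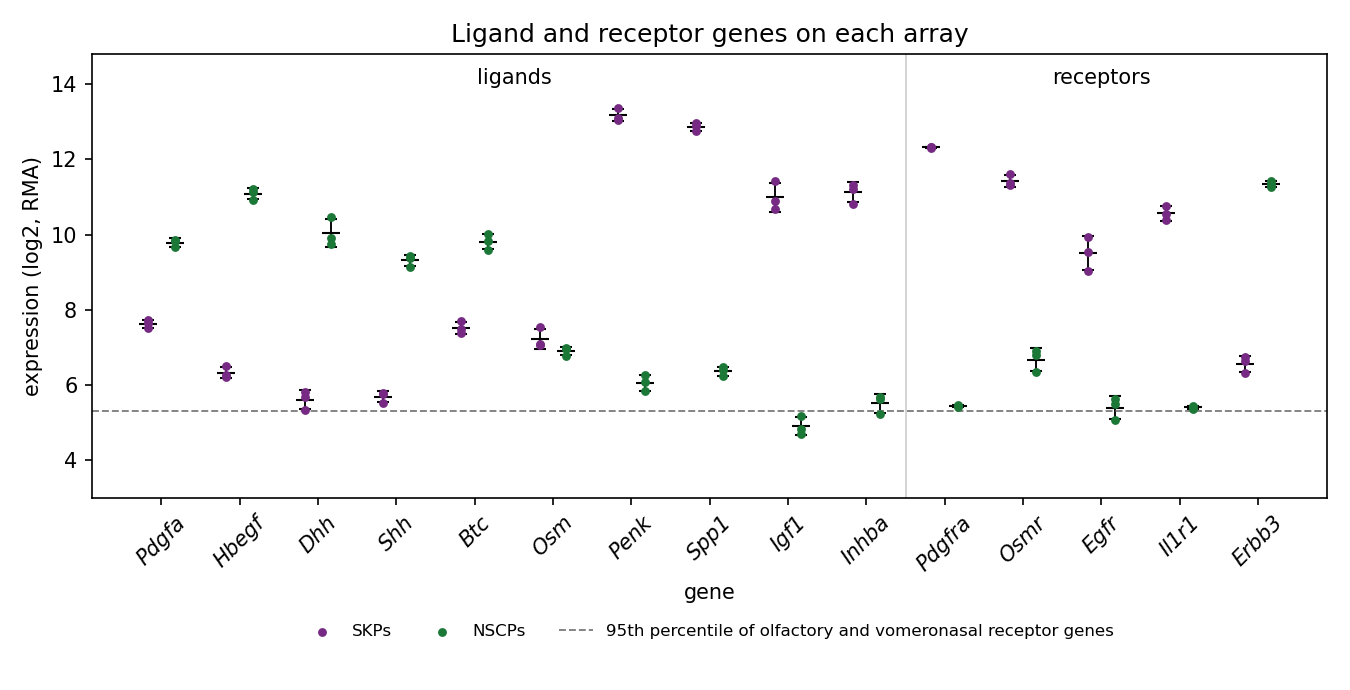
Log2 expression of 10 ligand genes and 5 receptor genes on each array (points; SKPs purple, NSCPs green), with mean and SD over 3 arrays as black bars and the background level of 5.32 as a dashed line. Pdgfa, Hbegf, Dhh, Shh, Btc and Erbb3 are higher in NSCPs, and the Osm points of the groups lie close together at means of 6.91 and 7.23.

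Proliferation genes were higher in NSCPs in 28 of 28 members, also when adjusted over the list alone, with differences from 0.60 to 3.31. Rrm2, which encodes a subunit of ribonucleotide reductase, was 9.90-fold higher, Uhrf1 8.69-fold, the mitotic cyclin gene Ccnb1 8.18-fold and the replication helicase gene Mcm6 6.31-fold. The proliferation list had an adjusted p of 1.61e-14 by camera, and the adjusted p was 0.171 with an estimated correlation. Cholesterol synthesis genes had 11 higher and 0 lower among 18, also when adjusted over the list alone; limma at an unadjusted p under 0.05 gave 0 lower too. Among them Idi1 (2.83-fold), Fdps (2.67-fold), Sqle (2.51-fold), Pmvk (2.49-fold) and Stard4 (2.38-fold) were higher. Camera gave an adjusted p of 0.00357, with an adjusted p of 0.382 with an estimated correlation.

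The media differ in FGF2 and EGF on the SKP side and in neuregulin-1β and forskolin, which raises cAMP, on the NSCP side. Which of these factors, or the cell type, moved the genes below was not tested. Genes induced by FGF and MAPK signalling had 11 lower and 3 higher in NSCPs among 18, also when adjusted over the list alone. The feedback phosphatase gene Dusp5 (-2.78), Egr1 (-2.41), the feedback inhibitor gene Spry1 (-2.00) and Il17rd (-1.68) were lower, and Phlda1 was higher (1.62). Camera's adjusted p was 0.00183, and the adjusted p was 0.333 with an estimated correlation. Genes induced by cAMP had 4 higher and 7 lower among 20, also when adjusted over the list alone, and were not called (adjusted p = 0.255); Nr4a1 was higher (2.79), and Rgs2 (-4.12), Dusp1 (-1.89), Sik1 (-1.31) and Star (-1.30) were lower.

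Markers of other cell types were measured in the same arrays. Macrophage and leukocyte markers were lower in NSCPs in 12 of 15 members and higher in 0, also when adjusted over the list alone; limma at an unadjusted p under 0.05 gave 0 higher too. Lyz2, Fcer1g (-6.52), Cd53 (-6.32), the leukocyte phosphatase gene Ptprc (-5.79) and Cd68 (-5.17) were among the lower members, and of these 5 Cd68 had an NSCP mean above background. Over the 14 members above background in SKPs, the mean in SKP replicates 1, 2 and 3 was 10.03, 8.98 and 9.33, and in the NSCP arrays it lay between 5.16 and 5.30. Camera's adjusted p was 1.36e-09, against an adjusted p of 0.234 with an estimated correlation. Adipocyte genes had 8 lower and 0 higher among 10 (9 and 0 when adjusted over the list alone; 0 higher at an unadjusted p under 0.05 in limma), with Lpl (-6.53), Fabp4 (-4.33), Adipoq (-4.25), Pparg (-3.82) and Cebpa (-1.69); the adjusted p was 8.71e-06 by camera and 0.234 with an estimated correlation. NSCP means of Lpl, Fabp4, Adipoq and Pparg were within background, and macrophages also express Lpl, Fabp4 and Pparg.

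With an estimated correlation 0 of the 31 lists passed in camera, and 7 had an unadjusted p under 0.05 there. The ligand list, with an estimated correlation of 0.0173, went from an unadjusted camera p of 2.41e-08 to 0.0092. The repair Schwann cell list, with an estimated correlation of -0.0436, went from 0.053 to 0.106 in camera. These rises therefore do not rest on correlation between genes alone. Under the preset correlation camera called 15 lists, 4 higher and 11 lower in NSCPs. Fry called 28, but it does not set a list against the other genes, of which many differed. It also called housekeeping genes (adjusted p = 0.00617 by fry), which camera did not (adjusted p = 0.749 by camera). Arl6ip1 was the gene whose called probe sets disagreed, with differences of 1.34 and -0.78, and it did not pass when they were averaged.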

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

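The counts over other splits of the arrays were planned before the data were examined. The report used probe sets with a single gene symbol, and signal was also present outside them. Of 17599 probe sets without a gene name here, 1378 differed at least 2-fold with a group mean above background, 440 higher and 938 lower in NSCPs. Among 575 probe sets with several gene names, 71 did, 45 higher and 26 lower. No explanation was tested for these.

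The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For each count or list shift below, 1 of the 10 splits, the real one, gave a result as large. The real split gave 7945 genes, 3167 at least 2-fold and 85 ligand genes, and the highest of the other splits gave 0 of each in limma, with up to 341 genes, 19 at least 2-fold and 2 ligand genes at an unadjusted p under 0.05. For the Schwann cell lineage list the negative log10 of camera's p was 5.73 against 3.02 at most in the other splits, and for dermal mesenchyme 13.69 against 6.16. Of the remaining 29 lists camera called 13 in the real split and up to 10 in another, so camera with the preset correlation also called many lists between mixed groups of arrays. Every other split mixes the cell types unevenly, so part of the real difference remains in it. These splits are therefore no reference without a difference.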

How the results depend on the processing

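The ligand list without leukocyte-expressed genes was chosen after seeing the data; every other alternative was planned. No called result changed direction in any alternative that was run. With an estimated correlation camera called 0 of the 29 lists besides the Schwann and dermal ones, against 13. That version also uses fewer degrees of freedom, so this drop does not measure the effect of correlation alone. Of all 31 lists, 7 had an unadjusted p under 0.05 in that test. Fry, which does not set a list against the other genes, called 28. Camera's adjusted p with an estimated correlation became 0.130 for Schwann cell lineage and 0.130 for dermal mesenchyme. Over the other alternatives these adjusted p ranged from 6.58e-07 to 1.84e-04 and from 8.38e-16 to 6.57e-08. Treat called 1758 genes, against 3167, by its stricter construction. The mean correlation between SKP and NSCP arrays, 0.881, became 0.686 and 0.735 with the filters on dim genes (median of all probes, background) and 0.907 over all probe sets, where other genes enter. Leaving out each array in turn gave 6341 to 7513 genes, 3142 to 3245 at least 2-fold, 80 to 85 ligands, 12 to 13 other lists, adjusted p of 6.58e-07 to 2.96e-05 (Schwann) and 7.5e-14 to 2.06e-12 (dermal), and correlations of 0.879 to 0.885. Same-numbered SKP and NSCP arrays had deviations correlated at 0.037, 0.050 and 0.028, and each array correlated best with its own number. The labels do not say whether a shared number marks a shared litter or day, and these small correlations do not settle it. With the replicate number as a block the counts were 7681 genes, 3170 at least 2-fold, 85 ligands and 12 other lists, with adjusted p of 2.95e-05 (Schwann) and 1.83e-12 (dermal). Median centring gave 8748 genes and 64.4% of calls higher in NSCPs, against 57.5%. Array weights gave 10426 genes, an adjusted p under 0.01 gave 5419, and the reduced ligand list had an adjusted p of 6.41e-05. The SKP marker list passed no more without SKP replicate 1 (0.0528), with the block (0.0584), on ranks (0.312), with either filter (0.0868, 0.0980) or with the trended prior (0.0513). The Hox list gained a call with the median filter (0.0359), and the stress list with adjustment over all probe sets (0.0464). Named genes lost their call in 40 of 2593 refits. Among them, with their differences in the main fit, were Flt1 (-1.19), Tbp (0.37), Actg2 (0.40), Pax7 (0.49), Dsg3 (-1.07), Cdh1 (1.08) and Rplp0 (0.63). The cause of these losses was not tested. Signal near background limits folds, as 570 of the 1813 genes at least 2-fold lower had NSCP means within background.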

Other observations

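Chosen after the results were seen were the test of array scaling, the test of co-variation of leukocyte genes, whose estimated correlation had already been computed, and the second neuronal test with its bound. Interferon-induced genes, which were not part of the comparisons above, had 14 members lower and 2 higher in NSCPs among 21, also when adjusted over the list alone. Psmb8 was 8.18-fold lower, Ifi27 8.13-fold and Ifit2 7.10-fold, and Ifi44 differed by -1.89, while Gbp2 was higher (1.74). Camera's adjusted p was 1.38e-04, and the adjusted p was 0.130 with an estimated correlation. Of the macrophage and leukocyte markers 12 of 15 were lower in the same arrays. Basal lamina and integrin genes had 10 higher and 9 lower among 29 (11 and 11 when adjusted over the list alone). The integrin genes Itgb8 (22.3-fold), Itgb4 (10.7-fold), Itga7 (10.5-fold) and Itga6 (4.84-fold) were higher in NSCPs, and Itga5, of the fibronectin receptor, was 9.01-fold lower; the list was not called (adjusted p = 0.923), with a median of 0.14, a mean of 0.35 and a test statistic on the lower side.

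Hypoxia and glycolysis genes had 6 higher and 3 lower among 19, also when adjusted over the list alone (adjusted p = 0.923 for the list), with Aldoc (3.03-fold), Egln1 (2.69-fold), Pfkfb4 (2.58-fold), Ldha (2.10-fold) and Pgk1 (2.08-fold) higher. Stress and apoptosis genes had 1 higher, Atf3 (1.80), and 7 lower, among them Hspb1 (-1.73), Cdkn1a (-1.54), Gdf15 (-1.11) and Mdm2 (-1.08), of 15 measured (3 and 9 when adjusted over the list alone; adjusted p = 0.0708 for the list, 0.0464 with adjustment over all probe sets). Housekeeping genes had 5 higher and 1 lower, B2m (-0.83), of 13 (5 and 2 when adjusted over the list alone; adjusted p = 0.749).

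Several lists of cell types that skin or nerve could bring along were not called. Perineurial and endoneurial fibroblast genes had 3 higher and 7 lower of 16 (4 and 8 when adjusted over the list alone; adjusted p = 0.0814), with Cldn1 (-5.41), Ntn4 (-1.48) and Sfrp2 lower and Itgb4 and Moxd1 (1.54) higher. Smooth muscle and pericyte genes had 1 higher and 4 lower of 12, also when adjusted over the list alone (adjusted p = 0.0977), with Cspg4 (-2.89) and Pdgfrb (-1.31) lower. Skeletal muscle genes had 1 higher and 2 lower of 14 (0 and 2 when adjusted over the list alone, with Tnnc1 at -1.55 and Chrna1 at -0.78; adjusted p = 0.873). Keratinocyte genes had 3 higher and 3 lower of 12, also when adjusted over the list alone (adjusted p = 0.923). Cdh1 (1.08) and Epcam (0.81) were higher, and Dsg3 (-1.07), Perp (-1.06) and Grhl3 (-0.60) were lower. Melanocyte genes had 4 higher and 2 lower of 11, also when adjusted over the list alone (adjusted p = 0.685), with Tyrp1 (1.40) and Dct (1.11) higher and Mitf (-2.43) and Mlana (-1.22) lower. Endothelial genes had 2 higher and 2 lower of 10, also when adjusted over the list alone (adjusted p = 0.873), with Tek (1.91) higher and Esam (-0.67) lower; their median of 0.05 and mean of 0.04 were above 0 and the test statistic below. Bone and cartilage genes had 2 higher and 3 lower of 15, also when adjusted over the list alone (adjusted p = 0.258), with Ibsp (2.33) higher and Spp1, Col11a1 (-2.99) and Runx2 lower; their median of 0.06 and mean of -0.58 differed in sign. Of the sex-linked list 1 gene was measured, Uty, at 9.46 ± 0.11 in SKPs and 8.70 ± 0.33 in NSCPs (SD, n = 3 each; adjusted p = 0.00757), and mitochondrially encoded genes were not analysed here. Means were within background for Tnnc1, Mlana and Dsg3 in NSCPs, for Tyrp1, Dct, Tek and Ibsp in SKPs, and for Epcam in both groups.

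Leukocyte genes were higher in SKPs, with a macrophage list median of -4.30, and a candidate explanation is leukocytes among the cells of the SKP cultures. In a separate leukocyte list 94.4% of the members, 17 of 18, were lower in NSCPs, among them Lcp2 (-6.10), Was (-5.42) and Spi1 (-4.76), named like Cd48 after their values were seen, and Cd48, at 12.12 in SKPs, differed by -0.12 and was not called. The macrophage markers C1qa (6.17 in SKPs, 6.33 in NSCPs), C1qb (5.57, 4.94) and Cd163 (within background in both), named after their values were seen, were not called either. Macrophage genes also varied together over the 3 SKP arrays (mean pairwise correlation 0.859, percentile 100 among 10000 random lists of like level), which leaves a share that differs between isolates open, because 7 of the 9 genes of the Schwann, crest, SKP, dermal, papilla and positional lists that varied as much, such as Sox2 and Rspo3, ranked the SKP arrays in the same order. Under the array scaling that brought it closest to 0 the median of the macrophage list stayed at -4.24. That test had little room for another outcome, because the values were already quantile normalized and scaling moved groups by 0.067. The median difference of all genes was 0.14. Quantile normalization keeps that median small, so it does not bound a shift common to all genes. Expression of these genes by SKPs themselves stays open.

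Neurofilament genes Nefl (5.04) and Nefm (4.65), known from neurons, were higher in NSCPs, while the fixed neuronal list with 4 higher and 3 lower of 14, also when adjusted over the list alone, was not called (adjusted p = 0.792). Neurons or axonal RNA carried from the nerve could account for this: a separate neuronal list had 7 members higher and 2 lower of 14 and a median of 0.36, with a bootstrap interval from -0.19 to 1.06, which did not decide it. A second test, added after that, used the fixed list without Nefl and Nefm. Its median was 0.016 with an interval from -0.60 to 0.36, below the Nefm difference of 4.65. This does not exclude whole neurons, because 7 of the 12 members were within background in NSCPs, where a small share of neurons might not show. Tubb3 (2.80) and, named after their values were seen, Sncg (3.71) and Calca (1.45) were higher in NSCPs, while Syn1 (-0.88) was lower. Whole neurons, RNA of axons, which need not hold all neuronal transcripts, and expression by the Schwann cell precursors themselves cannot be told apart here.

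Proliferation genes were higher in NSCPs, with a median of 2.21. Dilution of SKP transcripts by a non-dividing leukocyte share may contribute. The SKP array with the highest macrophage level, replicate 1, had rank 1, the lowest, in proliferation level. The remaining arrays did not follow the inverse order. Dermal list levels in SKP replicates 1, 2 and 3 were 10.78, 10.88 and 10.83, again lowest in replicate 1. Schwann list levels were 7.61, 7.13 and 7.36, highest in replicate 1, the opposite of what dilution would give. These 3 arrays are too few to decide. Dilution and a difference in division cannot be told apart, because the leukocyte share of the SKP RNA was not measured. Cell type and medium change together, so a difference in division could not be assigned to either.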
